A study of Mus musculus with 6 samples.

How the data were processed

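Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 6 libraries of mouse embryonic stem cells. The cells were E14 carrying an Nkx2-5-EmGFP reporter and were grown with leukemia inhibitory factor on a feeder layer of mouse embryonic fibroblasts, which was reduced by preplating, per the labels' protocols. Per the labels, 3 libraries came from control cells and 3 from Lmna knockout cells. The labels do not say whether the 3 libraries of a group are separate cultures or clones, so the deposited p-values measure the spread between these libraries, which may be technical.

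The submitters' processing notes name Trimmomatic 0.39, Bowtie2, SAMtools, Picard 1.119, deepTools, MACS2, bedtools 2.28.0, DiffBind, DESeq2 and ChIPseeker, and the build mm10. Their order and settings, the shift of reads for Tn5, the normalization and the model behind the p-values are not given in the sources used here. One table of the authors' comparison of the groups was used. Its log2 concentrations (the mean of both groups and of each group) and log2 fold are deposited as the authors computed them, and positive folds mean more accessible chromatin in the knockout cells. The direction was checked against the group concentrations, and the fold equalled knockout minus control within 0.01 at every peak. The p-value and FDR of each peak are the authors' deposited values. Gene symbols, annotation classes and distances to the transcription start site (TSS) are those of the deposited table, with 1-based mm10 coordinates.

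The table was sorted by p and held 65535 peaks. Multiplying FDR by rank and dividing by p gave 99078 tested peaks, so 33543 peaks, all with p above 0.422, are not analysed here. All peaks past an FDR of 0.05 are included, but medians over listed peaks leave out peaks with small changes. Values per library are not used here, so no test between libraries was run, replicate spread could not be computed and the depth per library is unknown. The planned branch for a table holding only the authors' comparison was followed.

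Peaks with an FDR of 0.05 or less were counted as gained or lost. Classes of location and chromosomes were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. The direction of neighbouring changed peaks was compared with 1000 shuffles within chromosomes. For 17 gene lists, genes with more gained than lost peaks were compared with all other changed genes by a two-sided Fisher exact test, adjusted over the lists. In these tests peaks and genes are the units and are not independent replicates. Genes were named by a rule: the 10 largest promoter gains and 10 largest promoter losses (within 3000 bases of a TSS, concentration at or above the median, predicted names left out), up to 3 members per list and direction with the smallest FDR, and all peaks of Lmna, Nkx2-5, Gata4, Gata6, Nanog and Pou5f1. These tests, lists and rule were set before the data were examined.

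Several steps were added after seeing the data. A scan for the contiguous segment of each chromosome that most reduced the sum of squares of log2 folds used peaks with a log2 concentration of at least 5, called strong peaks here. Counts were repeated outside the segment found on chromosome 14. The number of list genes with a gained peak was set against 10000 random lists matched on listed peaks per gene, and again on the median concentration of each gene's peaks as well. Peaks were also retested after centring on the median of listed folds, with standard errors implied by the deposited p under a normal test and peaks not listed held at a p of 1. Gene density came from RefSeq genes of GRCm38.p6, the assembly of mm10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

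The steps were tested on simulated data. Among 17625 genes, the Fisher test called 100.0% of 200 simulated lists whose 20 genes each received a lost peak, and 0.0% of lists whose genes each received a gained peak, because most changed genes already gained. Matched random lists called 100.0% of the lists of gained genes. Lists of other sizes were not simulated. The segment scan placed a boundary within 3 peaks of the planted one in 100.0% of 20 runs. The retest after centring was simulated on 99078 peaks in each of 2 settings. With a true offset of 0.45 and few true changes, 98.6% of its gained calls were true and 14.5% of its 1806 lost calls were false. With no offset and many small true gains, 100.0% of its 3333 lost calls were false. The median centred on was 0.6 in both settings, above the true offset in each.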

Results

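The data compare chromatin accessibility in Lmna knockout and control mouse embryonic stem cells, 3 libraries each. Lmna encodes lamins A and C, structural proteins of the nuclear lamina that bind chromatin. The study asks how loss of lamin A/C alters accessibility in naive pluripotent cells and at genes of the cardiovascular fate. All values per peak are the authors' group means, folds and FDR, and the depth per library is unknown.

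The Lmna locus itself was the first comparison, since it checks the labels. In the authors' deposited table, accessibility at chr3:88492472-88493370 (mm10), a peak inside Lmna that is annotated as a promoter, fell by 4.27 on the log2 scale in the knockout cells (FDR 4.44e-20). A second peak inside the gene, chr3:88503109-88503930, fell by 3.93 in that table (FDR 4.77e-07). Upstream of these, the authors' deposited log2 fold was 0.61 at chr3:88509424-88510368 in the 5' UTR (FDR 0.0209) and 1.52 at the intergenic peak chr3:88514529-88515460 (FDR 9.76e-05). The peak in the 5' UTR spans the upstream end of the gene, at 88509932, so accessibility there did not fall. The remaining peak, chr3:88473244-88473498, had a deposited log2 fold of -0.59 and did not pass (FDR 0.58). The gain in the 5' UTR did not hold after centring and retesting, where its log2 fold was 0.12. Accessibility does not show whether the protein was lost. At the targeted gene a fall of accessibility also cannot be told apart from a loss of the DNA itself.

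**Figure D1:**
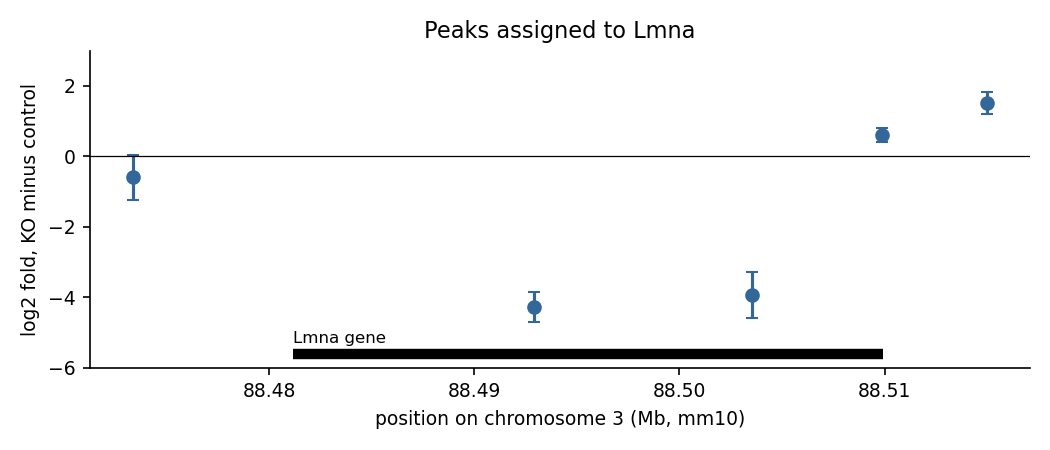
Authors' log2 fold (knockout minus control) of the 5 peaks assigned to Lmna against their position on chromosome 3 in Mb, with bars of 1 standard error implied by the deposited p and the gene as a black bar. Both peaks well inside the gene lie near -4, at -4.27 and -3.93.

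Across the genome, gains of accessibility outnumbered losses in the authors' deposited table. Of 12061 changed peaks, 10580 were gained and 1481 lost in the knockout cells, a gained share of 87.7% (exact 95% interval 87.1 to 88.3). The gains lay near 5072 genes and the losses near 1267 genes. The median gain was 1.46 on the log2 scale (quartiles 0.98 and 1.96), and the median loss was -1.91 (quartiles -2.51 and -1.37). At an FDR of 0.01 there were 5583 gained and 360 lost peaks, and at or above the median concentration 490 peaks were lost, with a median loss of -1.21. Distal chromosome 14 held 32.2% of the gained peaks, and outside it 7169 peaks were gained and 1477 lost (82.9% gained, 82.1 to 83.7), with a median gain of 1.19.

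The balance depended on the zero of the folds. The median log2 fold of listed peaks was 0.49. Counting the peaks not listed as 0 gave 0.0, a value fixed by that choice, so it does not estimate the offset. Retesting around 0.49, chosen after seeing the data, left 2930 gained and 5850 lost peaks, a gained share of 33.4%. The shift moves every peak alike, so retested counts of the gene lists below shift towards losses with it. In both simulated settings the median centred on was 0.6, above the true offset. Failing the retest is therefore weak evidence against a gain, and its lost counts may be too high. The simulations drew standard errors without regard to peak strength. Strong peaks outside distal chromosome 14 had a median log2 fold of 0.43, so the overshoot here may be smaller than simulated. Holding peaks not listed at a p of 1 also leaves out any losses among them. Of the gained peaks named by the rule for largest changes and lists, 28 of 50 kept their call; subtracting a positive offset cannot end the call of a lost peak. Direction also followed peak strength: outside distal chromosome 14, 33.6% of listed peaks with a mean log2 concentration below 3 had a positive fold, against 95.3% of those at 6 or more. The median log2 fold was -0.92 below 3, 0.57 from 3 to 4 and 0.4 at 6 or more. Above 3 the share of positive folds thus rose while the median fold of listed peaks did not. The limit on p keeps weak peaks mainly when their folds are large, so these medians cannot show whether size rose.

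**Figure D2:**
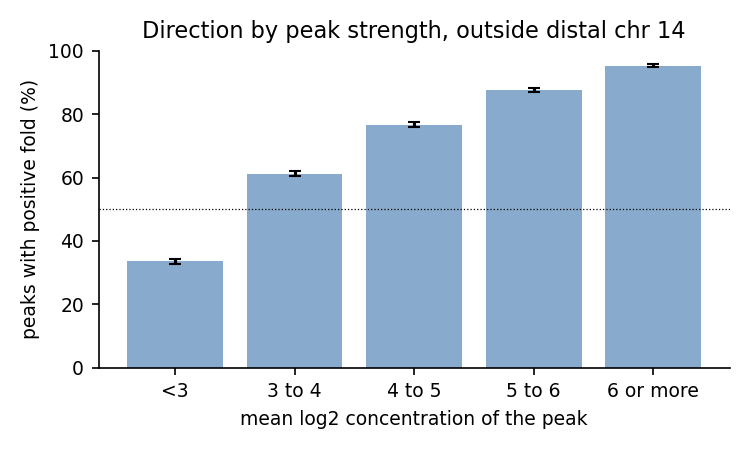
Percent of listed peaks with a positive fold by mean log2 concentration, outside distal chromosome 14, with exact 95% binomial intervals as bars and a dotted line at 50%. The share rises from 33.6% to 95.3%.

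Among promoter peaks at or above the median concentration, the largest gains outside distal chromosome 14 in the authors' deposited table were at Adap1 (log2 fold 3.32, FDR 3.49e-09), Twf1 (3.14), which encodes an actin-binding protein, Mras (2.99), a small GTPase of the Ras family, and Prodh (2.86), proline dehydrogenase. Inside distal chromosome 14 the same rule named Vwa8 (3.09), Ubac2 (2.72), Stk24 (2.69), Diaph3 (2.63), Kctd4 (2.62) and Klf5 (2.58). Among promoter peaks at or above the median concentration, the largest losses after Lmna in the deposited table were at Stmn2 (log2 fold -2.76, FDR 1.02e-10), a neuronal regulator of microtubules, Trit1 (-2.16) and Arhgef40 (-2.1). The other named losses were Cd5 (-1.76), Map2 (-1.69), a neuronal microtubule protein, Trdn (-1.6), Sall2 (-1.6), Fez1 (-1.56) and Dpp4 (-1.53).

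Promoters made up a larger share of gained than of lost peaks, and intergenic regions a smaller one. Of gained peaks, 20.1% were at promoters, against 14% of lost peaks (Fisher exact test, adjusted p = 6.71e-08), and 42.5% against 46.5% were distal intergenic (adjusted p = 0.0091). Of all listed peaks, 24.7% were at promoters and 37.6% were intergenic, so both changed sets held fewer promoters and more intergenic peaks than the listed ones. Outside distal chromosome 14 the gap was wider, at 26.9% against 14% for promoters (adjusted p = 6.76e-27) and 32.8% against 46.4% for intergenic peaks (adjusted p = 2.95e-22). Promoters were 26.3% and intergenic regions 35.5% of all listed peaks there. Downstream regions held 0.7% of gained and 1.7% of lost peaks (adjusted p = 0.00113), and exons, introns and UTRs did not pass. Among peaks with an absolute log2 fold of at least 1 the promoter difference was -1.4 points and the intergenic one 0.3 points, and at an FDR of 0.01 they were -0.4 and 0.2, so these calls did not hold there. At or above the median concentration the intergenic difference was -4.2 points and did not pass either (adjusted p = 0.159). The promoter difference held there (7.3 points, adjusted p = 0.00176) and within 1000 bases of a TSS (6.7 points, adjusted p = 2.7e-12). The settings by fold, FDR, concentration and distance included distal chromosome 14. Outside it, at or above the median concentration, both differences held (13.1 and -11.0 points). The limits on fold and FDR were not repeated outside it.

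Chromosome 14 stood apart. Over its distal 49.5 Mb, chr14:75130556-124676281, 3411 peaks were gained and 4 were lost. Strong peaks there had a median log2 fold of 1.66 (815 peaks), against 0.43 on the chromosome before this segment (402 peaks) and 0.43 elsewhere in the genome (17010 peaks). The difference was 1.23 (bootstrap 95% interval 1.19 to 1.27), or 2.35-fold. The segment holds Klf5, a factor of naive pluripotency with 31 gained peaks, and Zic2, a formative gene with 4. On chromosome 14 as a whole 98.8% of changed peaks were gained, against 83.0% elsewhere (adjusted p = 5.07e-175), and before the segment 81.0% were.

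**Figure D3:**
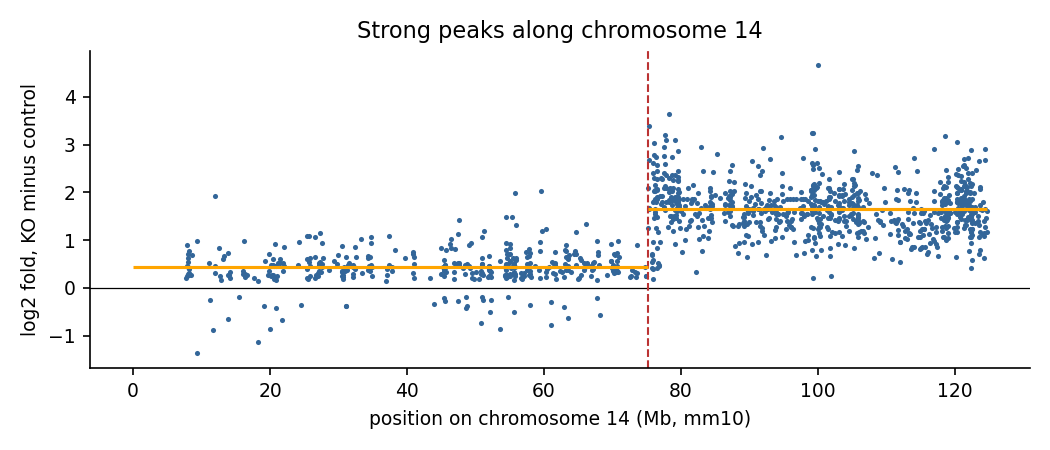
Authors' log2 fold (knockout minus control) of each strong peak on chromosome 14 against its position in Mb; orange lines are medians and the dashed line is the start of the segment. The median steps from 0.43 to 1.66, and some peaks just after the line still lie near the lower level.

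Outside the segment, chromosome 17 had a higher gained share than the rest (89.5% against 82.6%, adjusted p = 0.00529), and chromosomes 3 (78.1%) and 10 (77.5%) had lower ones, both with an adjusted p of 0.0191. Neighbouring changed peaks went the same way in 76.1% of pairs outside the segment, against a mean of 71.8% in shuffles (permutation p = 0.001, the smallest that 1000 shuffles can give). With the segment the values were 82.8% and 79.6%.

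Naive pluripotency genes, which maintain the ground state of these cells, had more gained than lost peaks in the deposited table. Of 20 genes with a listed peak, 16 had a gained peak and 2 a lost one, with 72 gained and 2 lost peaks. Of the gained peaks, 31 were at Klf5 in distal chromosome 14. Adjusted over the list alone, there were 92 gained and 6 lost peaks, and 18 genes had a gained and 6 a lost peak. In the authors' deposited table the strongest members outside distal chromosome 14 were Esrrb (log2 fold 1.89 at its promoter, FDR 1.05e-12), with 10 gained peaks, and Tfcp2l1 (2.8, FDR 8e-08), with 6. Klf5 had a deposited log2 fold of 2.49 (FDR 3.36e-65) within the segment. Nanog had 2 gained peaks and 1 lost peak, chr6:122667329-122668076 (deposited log2 fold -1.05, FDR 0.0249), and its promoter did not pass (0.4, FDR 0.336). Pou5f1 gained at its promoter (deposited log2 fold 0.98, FDR 0.0294), its other 3 peaks did not pass, and Dppa3 lost 1 peak (-1.08, FDR 0.0489). The gains of Nanog and Pou5f1 did not pass the retest after centring, where their log2 folds were 0.11, 0.47 and 0.49. The planned comparison with other genes did not pass (adjusted p = 0.843), in a test that called none of the simulated lists of 20 gained genes. Against random lists matched on listed peaks, a test chosen after seeing the data, 16 genes stood beside a mean of 10 (adjusted p = 0.0561), and outside the segment 15 beside 9.1 (adjusted p = 0.0442). With concentration matched as well, the means were 12.4 and 11.4 and neither passed (adjusted p = 0.666 and 0.716). After centring and retesting, the list had 28 gained and 12 lost peaks, and outside the segment 7 gained and 12 lost.

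Formative and primed genes, which mark the exit from the naive state, were split between gains and losses in the deposited table. Of 16 genes, 6 had a gained and 4 a lost peak, with 10 gained and 7 lost peaks, the same counts as adjusted over the list alone. After centring and retesting there were 4 gained and 22 lost peaks, with 0 gained outside the segment. In the authors' deposited table Dnmt3a (log2 fold -2.61, FDR 0.000561), a DNA methyltransferase, Lef1 (-1.85, FDR 0.00208) and Sall2 lost peaks. Foxd3 (1.13, FDR 5.45e-05) and Etv4 (1.2, FDR 0.00588) gained peaks in the same table, but neither passed the retest, at centred log2 folds of 0.64 and 0.71. Foxd3 also lost a distal peak, chr4:99516845-99517115 (deposited log2 fold -3.0, FDR 0.00911), and Zic2 gained in the segment (2.4). Against other genes the list did not pass (adjusted p = 0.585). Outside the segment the naive and formative lists differed in peaks, 41 gained and 2 lost against 6 and 7 (Fisher exact p = 0.000212). In genes the difference did not pass (Fisher exact p = 0.0909). This comparison was chosen after seeing the data and did not match concentration. The peak counts took peaks of the same gene as separate units, among them 10 gained at Esrrb.

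Cardiovascular genes changed at some loci and did not pass as lists. Of 15 cardiac transcription factor genes, 7 had a gained and 2 a lost peak (adjusted p = 1.0). In the authors' deposited table Hopx (log2 fold 2.1, FDR 8.39e-09) and Tbx20 (1.78, FDR 6.36e-08) gained, Mef2c lost a distal peak (-1.5, FDR 0.0287), and Tead1 had one of each, of which the gained one did not pass the retest (centred log2 fold 0.63). Gata4 gained intronic peaks (deposited log2 fold 3.05, FDR 0.0105, and 0.9, FDR 0.0218) and Gata6 distal ones (1.43 and 1.89), and the promoters of both did not pass (FDR 0.308 and 0.18). After centring and retesting, the larger Gata4 gain passed (centred log2 fold 2.56, adjusted p = 0.0482), and the smaller one (0.41) and both of Gata6 (0.94 and 1.4) did not. Neither listed peak of Nkx2-5, the locus of the reporter, passed (deposited FDR 0.266 and 0.497). Of 19 genes for heart muscle structure, 6 had a gained and 2 a lost peak (adjusted p = 0.843). Adjusted over the list alone, 11 had a gained and 3 a lost peak, while the other cardiovascular lists kept their gene counts. Cacna1c, a calcium channel subunit, gained an intronic peak (deposited log2 fold 3.31, FDR 3.24e-16), as did the promoters of Nppb (2.13) and Myl4 (1.8), while Tpm1 (-1.93) and Ryr2 (-1.23) each lost one. Of 16 endothelial genes 4 had a gained peak, among them Vwf (1.73, FDR 5.24e-10), and Kdr lost one (-1.62) in the deposited table (adjusted p = 0.854). Smooth muscle went the other way, with 1 gene gained and 3 lost of 10, Acta2, Itga8 and Tpm2 (deposited log2 folds -1.17, -1.23 and -2.32), and did not pass after adjustment (Fisher exact p = 0.0116, adjusted p = 0.0988). After centring and retesting, cardiac factors had 3 gained and 11 lost peaks, heart muscle structure 6 and 3, endothelial genes 1 and 4, and smooth muscle 0 and 5.

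**Figure D4:**
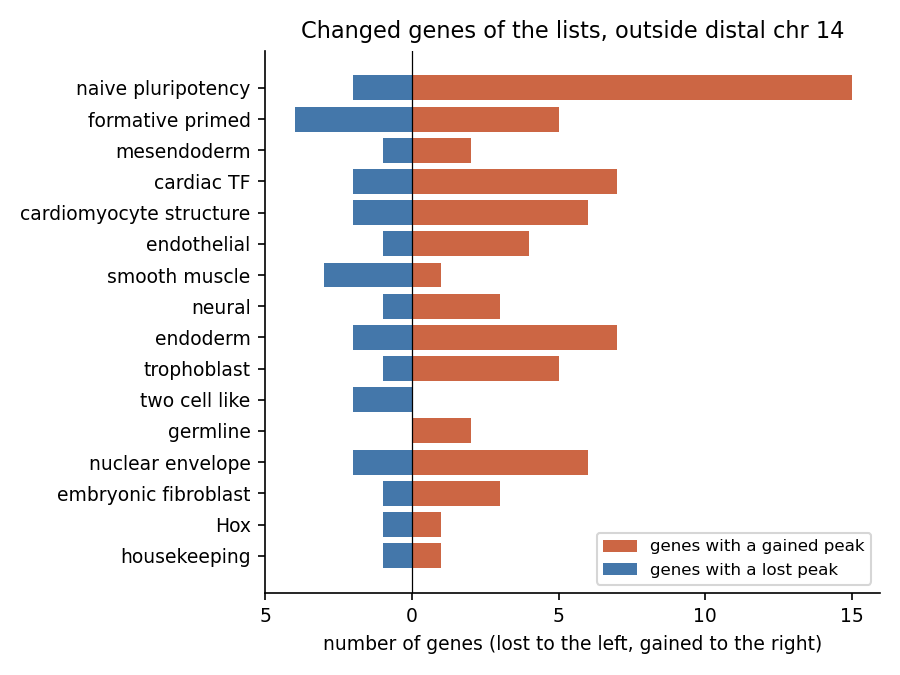
Number of genes with a gained peak (right, orange) and with a lost peak (left, blue) in 16 of the 17 lists, outside distal chromosome 14; a gene with both counts on each side. The naive list has 15 gained genes and 2 lost ones.

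Of all 17625 genes with a listed peak, 28.8% had a gained and 7.2% a lost peak in the deposited table. Genes with a gained and with a lost peak numbered 2 and 1 of 13 for mesendoderm, 3 and 1 of 13 for neural genes, 7 and 2 of 15 for endoderm, and 5 and 1 of 12 for trophoblast. Germline genes numbered 2 and 0 of 10, nuclear envelope genes 6 and 2 of 14, Hox genes 1 and 1 of 28, and housekeeping genes 1 and 1 of 15, where Actb held both. Embryonic fibroblast genes, a marker of the feeder layer, numbered 3 and 1 of 16. None of these lists passed the Fisher test (the smallest adjusted p was 0.843), which says little about a lean towards gains. Against random lists matched on listed peaks, none passed for genes with a gained peak either. Two-cell-like genes had 0 gained and 2 lost of 9, Zfp352 and Usp17la (adjusted p = 0.125). Chemoreceptor genes had 46 gained and 19 lost of 502, a lower gained share than other genes at 71.9% against 85.3% that did not pass after adjustment (adjusted p = 0.0988), and passed among peaks of higher concentration (adjusted p = 0.00175). After centring and retesting, lost peaks outnumbered gained ones in each of these lists, as they did over all peaks, for example 12 against 2 for endoderm, 4 against 3 for trophoblast and 91 against 7 for chemoreceptors.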

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

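Settings that leave out distal chromosome 14, retest after centring or match concentration were chosen after seeing the data, and the cause of a change was not tested unless named. No paired analysis was possible because the table holds group means and no values per library. For the same reason the edgeR fit planned for read counts, a DESeq2 fit and leaving out each replicate were not run. The main design held no replicate block, because the labels do not say that replicate numbers pair the cultures. At an FDR of 0.01 there were 5583 gained and 360 lost peaks (93.9% gained), with a median gain of 1.64. With an absolute log2 fold of at least 1 the gained share was 85.2%. At or above the median concentration it was 93.8%, with 490 lost peaks and medians of 1.18 and -1.21. Centring on the median of listed peaks gave 86.7%, and retesting after it 2930 gained and 5850 lost (33.4%), the one setting that turned the balance. The offset of this retest may be too large. The 33543 peaks not listed all have p above 0.422, and the median centred on overshot the true offset in both simulated settings. Those settings drew standard errors without regard to peak strength, and strong peaks outside distal chromosome 14 had a median log2 fold of 0.43. Outside distal chromosome 14 the gained share was 82.9% and the median gain 1.19, and chromosome 14 stood -1.9 points from the rest. The promoter difference was -0.4 points at an FDR of 0.01 and -1.4 points at an absolute log2 fold of 1, but held at higher concentration (7.3 points). The intergenic one was 0.2, 0.3 and, at higher concentration, -4.2 points, where it lost its call (adjusted p = 0.159). Outside distal chromosome 14 at higher concentration both held (13.1 and -11.0 points). Of the lists, 3 passed when peaks were counted (naive, formative, chemoreceptor), 1 of them (formative) outside distal chromosome 14, and 1 (chemoreceptor) at higher concentration. The naive excess over random lists fell from 5.9 to 3.6 genes outside distal chromosome 14 when concentration was matched, and lost its call. Of 109 list values recomputed, 19 changed sign without a call. The Lmna peak in the 5' UTR had a log2 fold of 0.12 after centring, and the intergenic gain kept its call. Neighbouring peaks stayed above shuffles in all 4 settings. With depth unknown, the precision of single peaks rests on the deposited p.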

Other observations

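Genes in this and the next paragraph were chosen after their values were seen. In the authors' deposited table the smallest FDR outside distal chromosome 14 belonged to Erdr1, with 4 gained peaks on chromosome Y (log2 fold 1.29 and FDR 2.01e-42 at chrY:90807188-90811853), of which 3 passed the retest after centring. All 8 changed peaks of chromosome Y, these 4 among them, were gained, and its 24 listed peaks had a median log2 fold of 1.31. Intergenic peaks nearest Glra1 (deposited log2 fold 2.11, FDR 1.92e-21), Smim31 (2.62, FDR 4.44e-20) and Nkx6-3 (2.42, FDR 1.48e-18) followed. Bvht, the Braveheart long noncoding RNA known for its role in cardiac commitment, gained 3 peaks, including its promoter (deposited log2 fold 1.04, FDR 0.00127), which did not pass the retest after centring (0.55).

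Among lost peaks the deposited table listed peaks nearest Irgm1 (log2 fold -3.39, FDR 5.14e-07), an interferon-inducible GTPase, Ythdf3 (-2.08, FDR 2.37e-06) and Ppp3ca (-1.88, FDR 1.02e-05). On chromosome 17, 23 strong peaks between 15989946 and 21384200 had a median log2 fold of -0.22, against 0.43 on the rest of that chromosome.

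Of the tests below, library scaling on chromosome 14 and all 3 on peak strength were chosen after the result was seen. For the gain over distal chromosome 14 the values argue against library scaling, since strong peaks inside exceeded those elsewhere by 1.23, and against an opening of gene-poor chromatin, since the fold hardly followed gene density (Spearman rho 0.05 across peaks). Promoter and intergenic peaks inside differed by 0.0 in median log2 fold (bootstrap interval -0.08 to 0.08), by 0.12 among strong peaks (0.02 to 0.19) and by -0.04 at matched concentration (-0.15 to 0.06), all within the 0.2 that a copy number gain in the knockout cells allows. For comparison, 3, 4 and 5 copies against 2 give 0.58, 1.0 and 1.32, and 2 against 1 gives 1.0, but peaks that are not listed are missing from the 1.23, so no copy number is read from it. Listed peaks numbered 97.5 per Mb inside, against 18.6 on the chromosome before the segment. Of all tested peaks 66.1% are listed, so the limit on p alone is unlikely to give this gap. More peaks called inside could follow from a shift of either kind, so the density does not separate the explanations. A domain-wide opening that acts alike on all peaks remains open, since no DNA copy number was measured here.

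Outside that segment the gained share of changed peaks rose with concentration, from 44.8% below a log2 concentration of 3 to 98.5% at 6 or more, and losses outnumbered gains below 3 (532 against 432). Above 3 the median log2 fold of listed peaks went from 0.57 to 0.4. The limit on p keeps weak peaks mainly when their folds are large, so these medians cannot show whether size rose. One offset between the groups as the whole cause is argued against, because 33.6% of the weakest listed peaks had a positive fold. The segment as the cause is argued against too, since with it left out the gained share still differed by 53.6 points between these levels (bootstrap interval 50.4 to 57.0). A different share of reads in peaks between the groups could give such a trend and cannot be told apart from a biological one. Its test met the bound set against it, a rho of -0.02 in promoters, but is void: the limit on p alone gives -0.25 when no trend is simulated, and positive promoter folds rose from 30.9% to 96.8% with concentration.

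Losses may follow gene-poor neighbourhoods. Distal chromosome 14 was left out of all values in this paragraph. At matched concentration, the lost share of changed peaks was higher in the gene-poorest quartile (at most 5 coding genes within 500 kb) than in the gene-richest (at least 16) on 19 of 20 chromosomes. Per listed peak, which leaves out peaks of large p, 3.3% were lost in the gene-poorest quartile and 1.7% in the gene-richest, again higher on 19 of 20 chromosomes, while 11.8% and 11.3% were gained (higher on 12 of 20); these rates were chosen after the result was seen. Annotation class was not matched. Lost peaks were more often distal intergenic than gained ones, at 46.4% against 32.8%, so the pattern may restate that difference. Lamina-associated domains are gene-poor, so a loss of lamin contact is a candidate explanation for the pattern, as is any other property of gene-poor DNA. No map of lamin binding was analysed here.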
